A study of Mus musculus with 4 samples.

How the data were processed

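Primary cortical oligodendrocyte progenitor cells treated with CNTF were used for ChIP-seq with an antibody against tyrosine-phosphorylated STAT3, in 2 ChIP libraries with 2 inputs. The inputs were not analysed here, and the labels do not say which input served which ChIP. Reads were handled with CASAVA 1.8 and Bowtie2, and peaks called with MACS2, on genome build GRCm38.p3, per the submitters' processing notes, which give no options. The authors deposited 1 peak list per ChIP library, so the peaks are taken as called per sample, and 1 table of reproducible regions for both.

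In the peak lists, the pileup signal is the number of fragments stacked at the summit, per the file headers. The fold enrichment was computed by the authors' peak caller, per the file headers, and the values are those of a ratio of the pileup to the local background with 1 added to each. Headers of a pair of further columns are damaged in the deposited lists: from their values and place they hold the -log10 p and the -log10 q of each peak. The -log10 p was recomputed from the pileup and the fold by the upper tail of a Poisson distribution, and matched within 0.1% for 99.6% of replicate 1 peaks and 99.985% of replicate 2 peaks. The lowest -log10 p was 3.01 and 3.04; the caller's threshold is not given in the sources used here, and 0.001 was used where peaks were called again after thinning. In the deposited region table, the column headed adjusted p-value holds the IDR by the table's title, and no region has an IDR above 0.05 in it. Its columns headed fold enrichment and pileup are identical and hold the mean -log10 p of the replicates in 12924 of 12925 regions, within 0.001, so they were not used as fold enrichments, and its summit column is the region's midpoint. Each region was given the fold enrichment of the strongest overlapping peak of each replicate. Positions are 1-based.

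Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Transcription starts and 3' ends were taken from the Ensembl transcripts in the authors' table, which lists those within 25 kb of a region and the nearest transcript. The background for gene lists was the 21883 protein-coding genes on chromosomes 1 to 19, X and Y of a RefSeq gene table of the same assembly at a later patch level (GRCm38.p6), matched by symbol or by a synonym of a single gene. Of 10013 pairs of a region and a reference gene within 5 kb, the authors' table named 96.8%. That table has no strand or exons and no genome sequence was used here, so the planned motif counts, exon and UTR classes and CpG or GC matching were not run, and the planned comparison of starts with random placements was made with either end of a gene. Random placements lay between the outermost gene or peak of each chromosome, since chromosome lengths were not used here, and gaps in the assembly were not removed, which lowers the random shares near genes.

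Overlap was at least 1 bp, tested against 1000 random placements. Differences of medians were tested with 100000 permutations. The comparison of starts with 3' ends, of upstream with downstream regions and of strength by distance from a start were added after the data were seen. Gene lists were tested with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 17 lists, for a region midpoint within 5 kb of a start. Alternatives were an IDR of 0.01, overlap of at least 50% of each peak, summits within 100 bp, a -log10 q of at least 10, equal numbers of peaks, each replicate alone, the stronger 6462 regions, and windows of 1 and 25 kb. The steps were tested on simulated data: with 50% of 42131 peaks planted on a partner, 50.3% were recovered, 4.25% of random gene lists among 21883 genes had p under 0.05, and 100% of planted lists passed. Lists were planted only at a share of slightly over 50% of their genes, so power at lower shares was not tested.

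Before the data were examined, the named genes were set as the 25 genes nearest to the strongest regions within 5 kb of a protein-coding start, up to 4 members of each list with the strongest regions, the 5 strongest regions farther away, and Socs3, Stat3, Junb, Fos, Bcl3, Gfap, Mbp and Olig2. Strength was the lower fold enrichment of the replicates. Other genes named in the text were chosen after their values were seen. The number of reads per library is not given in the sources used here, so depth is known only through the caller's background. Intervals cover counting error over genes or regions only. Peaks on the mitochondrial genome and on scaffolds were left out of the comparisons.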

Results

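Phosphorylated STAT3 (pSTAT3) was mapped by chromatin immunoprecipitation and sequencing in primary cortical oligodendrocyte progenitor cells of C57BL/6 mice, the proliferating cells that give rise to myelin-forming oligodendrocytes. The cells were grown in 10 ng/ml PDGF-AA and 20 ng/ml bFGF, which keep progenitors dividing, and received 100 ng/ml of the cytokine CNTF for 15 min. CNTF acts through the gp130 receptor and JAK kinases, which phosphorylate STAT3. The series holds 2 pSTAT3 ChIP libraries and 2 input libraries, all from treated cells, so the comparisons are between ChIP replicates, between bound regions and genes, and between groups of genes. The deposited lists held 42189 peaks for replicate 1 and 26649 for replicate 2, with a median width of 301 and 272 bp and a median height of 30 and 20 stacked fragments at the summit. The lowest background used by the peak caller was 4.72 fragments in replicate 1 and 2.91 in replicate 2, a ratio of 1.62, and is the measure of depth that the lists give. Fold enrichments are the authors' values per peak, relative to local background. No label states that the libraries came from separate cultures, and the protocol describes pooling of lysed cells, so the spread between them may be technical.

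By the lower of both fold enrichments, the strongest reproducible pSTAT3 region lay at the promoter of Stat3 itself. It covered chromosome 11, 100938836 to 100940313 (GRCm38), with its midpoint 34 bp upstream of a listed transcription start of Stat3 (ENSMUSG00000004040), and had a fold enrichment of 57.0 in replicate 1 and 73.5 in replicate 2. Its pileup was 325 fragments in replicate 1 and 286 in replicate 2, where the highest of any peak was 326 and 302. In replicate 1, Gfap (314), Map3k1 (307) and Junb (303) also came near 326, while Socs3 (284) and Akt2 (272) lay lower. Local background moves the fold as well: Rpl22 had 301 fragments there but 30.3-fold enrichment. Whether the pileup has an upper limit was not tested, so the order of the strongest regions is uncertain. Socs3, the feedback inhibitor of JAK-STAT signalling, carried a region of 49.9-fold and 49.2-fold enrichment at chromosome 11, 117966894 to 117970258. This region spanned the start at 117969186, and its midpoint lay inside the gene, 610 bp downstream. Distances of regions from starts are those of midpoints throughout. The gp130 receptor gene Il6st had a region 51 bp upstream of its start with 44.1-fold and 36.4-fold enrichment, and Cish, another feedback inhibitor, had one 18 bp upstream with 29.9-fold and 23.3-fold. Some loci held several regions, with 8 within 25 kb of a Socs3 start, 6 within 25 kb of Junb and 3 within 25 kb of Stat3, whereas Il6st and Cish had 1 each. Beside the promoter, Socs3 had a region of 41.5-fold or more in both replicates 5.96 kb upstream of the start. Another of 35.2-fold or more lay 5.62 kb downstream.

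**Figure D1:**
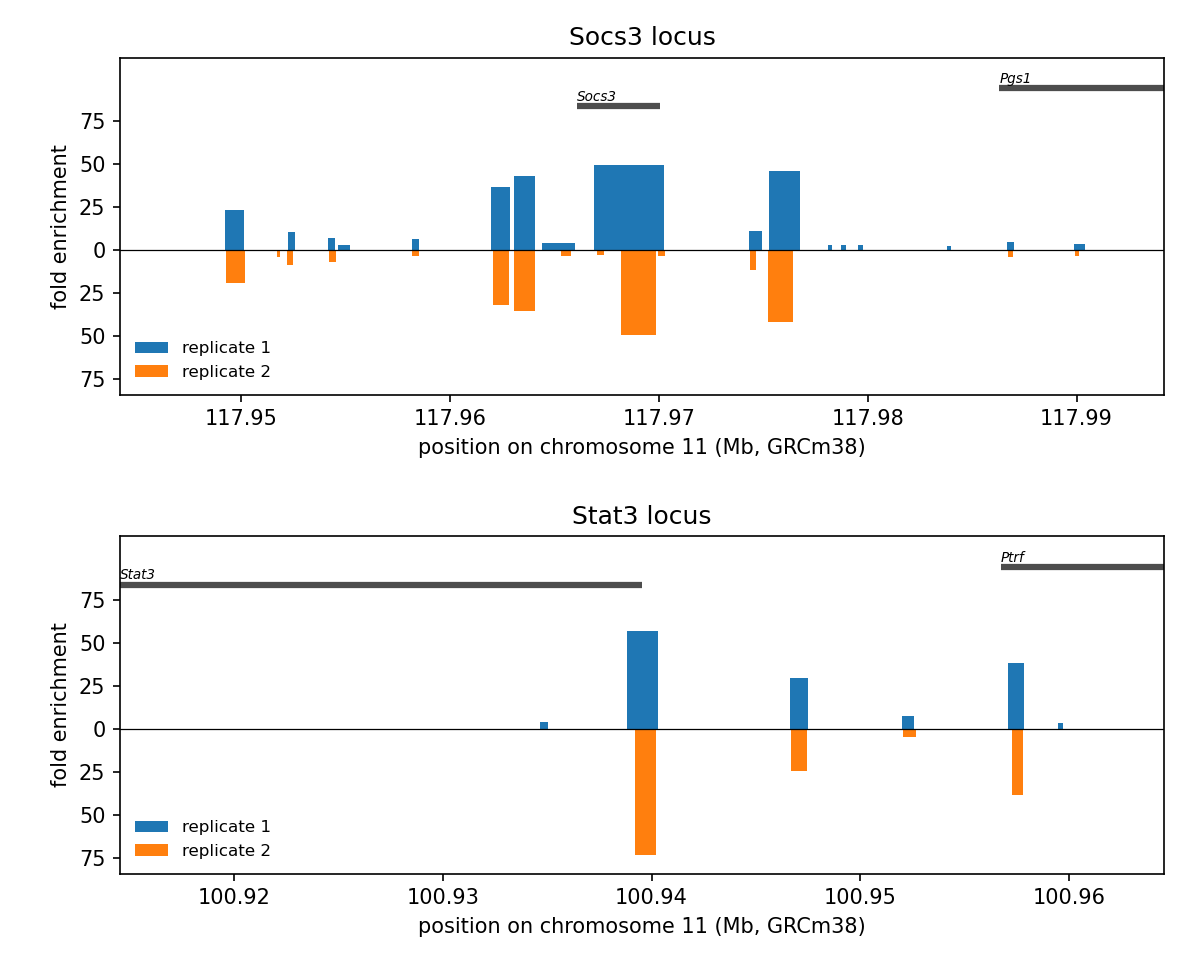
Peaks within 25 kb of a transcription start of Socs3 (top) and Stat3 (bottom) on chromosome 11. The x axis is the GRCm38 position in Mb; each bar spans a peak and its height is the fold enrichment at the summit, replicate 1 upward and replicate 2 downward, and grey lines are transcripts. The highest peaks in each window lie at the promoters, with 49.9-fold and 49.2-fold enrichment at Socs3 and 57.0-fold and 73.5-fold at Stat3.

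The replicates were compared to see how far the peak lists share sites. Of the 26537 replicate 2 peaks on chromosomes 1 to 19, X and Y, 24488 (92.3%) shared at least 1 bp with a replicate 1 peak, and 23827 of 42131 replicate 1 peaks (56.6%) shared at least 1 bp with a replicate 2 peak. Random placements of the peaks on their own chromosomes gave means of 1.21% and 0.756%, and none of 1000 placements reached the observed shares (one-sided permutation p = 0.001 for each list, the smallest that 1000 placements can give). Peaks with a partner were stronger than those without, at a median of 6.85-fold against 3.67-fold in replicate 1 and 5.12-fold against 3.33-fold in replicate 2 (two-sided permutation p = 1e-05 for each list, the smallest that 100000 resamples can give; peaks are not independent replicates). Over 23827 pairs of overlapping peaks, the log2 fold enrichments of the replicates had a Spearman's rho of 0.86 and a Pearson's r of 0.908, as a description across peaks.

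**Figure D2:**
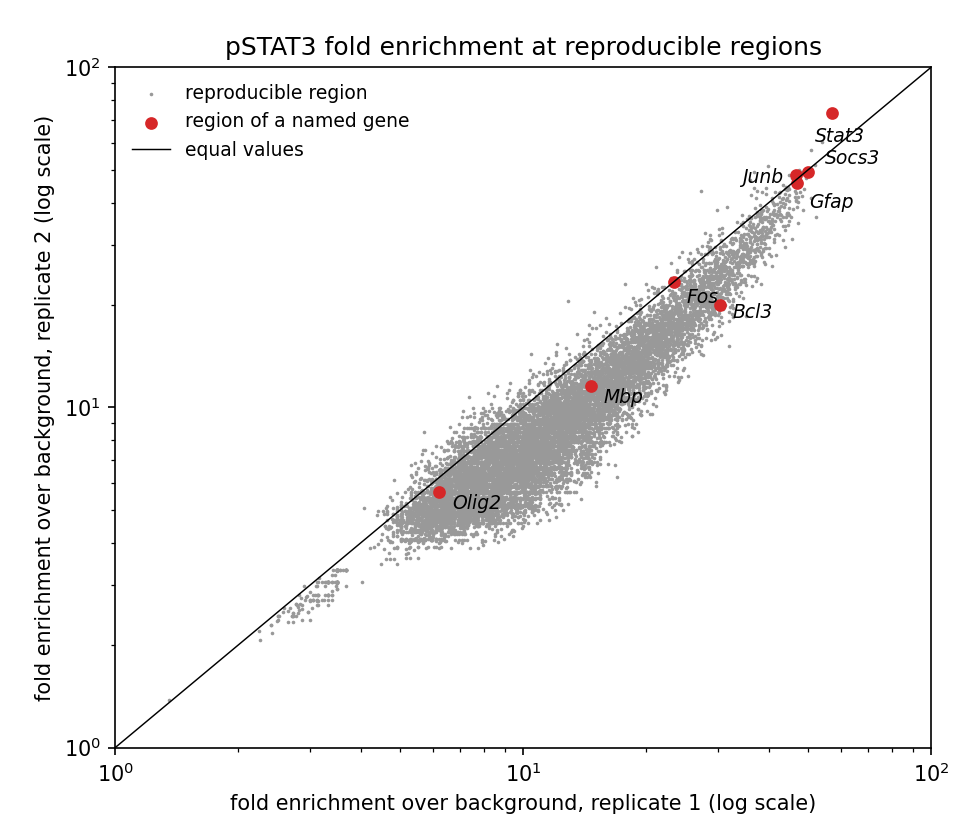
Fold enrichment of the 12925 reproducible regions in replicate 1 (x axis) and replicate 2 (y axis), both on log scales. Grey points are regions, red points the regions of 8 genes named in advance, and the line marks equal values. Each named gene is shown by its strongest region within 5 kb of a start, and Mbp, which has none, by a region 33.1 kb away. Stat3 lies highest, at 57.0-fold and 73.5-fold, and Olig2 lowest of the named genes, at 6.23-fold and 5.64-fold. A stronger Olig2 region, 36.7-fold and 27.6-fold, lies 8.01 kb downstream and is not among the red points.

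The authors' table of reproducible regions held 12925 regions with an irreproducible discovery rate (IDR) of 0.05 or below, of which 10250 had an IDR of 0.01 or below. Their median fold enrichment was 10.4 in replicate 1 and 7.51 in replicate 2, and their median width was 504 bp. A group of 145 regions stood apart at the weak end, with a mean -log10 p of 3.53 to 6.22, while the next region had 11.5. This group had a median fold enrichment of 3.32 and 2.92.

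Reproducible regions gathered at transcription starts. The midpoints of 3092 regions (23.9%, 95% Wilson interval 23.2 to 24.7%) lay within 1 kb of a start, among them the strongest regions of Stat3, Socs3, Akt2, Etv6 and Gfap, whereas 1017 (7.87%) lay within 1 kb of a transcript's 3' end. Regions near a start only outnumbered those near a 3' end only by 2569 to 494 (exact McNemar test, two-sided, -log10 p = 336). A further 5229 regions (40.5%) lay inside a transcript and 4604 (35.6%) outside transcripts. Within 1 kb of either end of a gene lay 23.4% of regions against a mean of 6.37% for random placements, a ratio of 3.67 (two-sided permutation p = 0.002, the smallest that 1000 placements can give), and 64.7% lay inside a gene against 48.7%. Near starts, 1699 midpoints were upstream, 1375 downstream and 18 at the start itself (exact binomial test, two-sided, p = 5.51e-09). The median offset was small, -16.5 bp, with negative values upstream. Each midpoint was counted by its nearest listed start, so those between divergent starts count as upstream whichever is nearer. Regions within 1 kb of a start were no stronger than those over 25 kb away by a detectable margin, with a median lower fold of 7.54 and 7.48 (two-sided permutation p = 0.6).

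**Figure D3:**
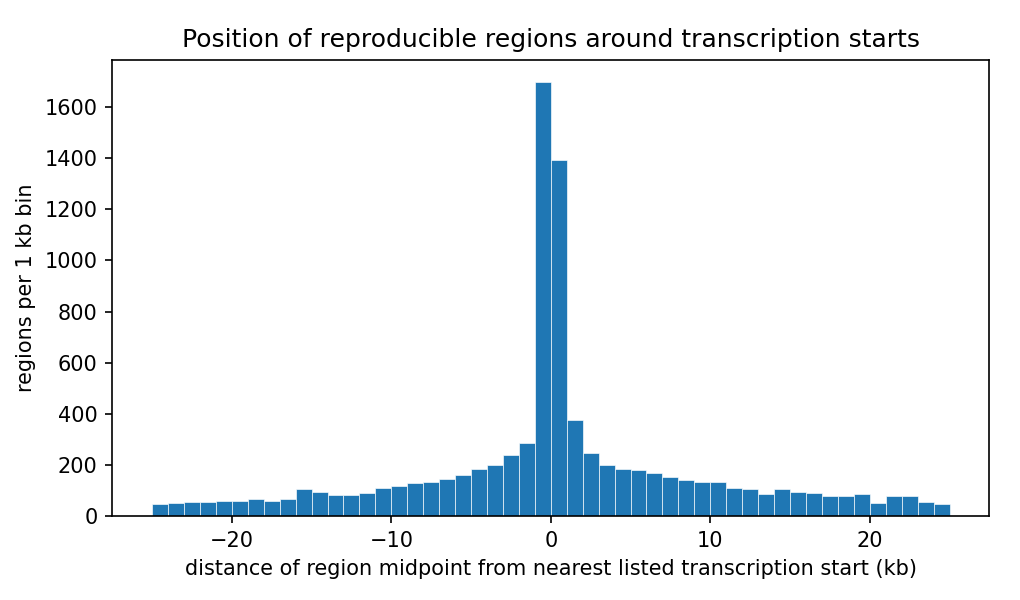
Number of reproducible regions per 1 kb bin (y axis) by the distance of their midpoint from the nearest listed transcription start in kb (x axis, negative values upstream). The bins next to the start hold 1699 regions upstream and 1393 at or downstream of it, 18 of them at the start itself, against 284 and 376 in the bins that follow.

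The 25 genes with the strongest regions within 5 kb of a start had a fold enrichment of at least 38.3 in both replicates. Signalling genes among them were Stat3, Socs3, Map3k1 (48.7-fold and 50-fold, 758 bp upstream), a kinase of the JNK pathway, Akt2 (47.8-fold and 47.9-fold, at the start), a kinase that acts in insulin and survival signalling, and Tnik (44.9-fold and 42-fold, inside the gene). Transcription factors were Junb (46.6-fold and 48.3-fold, 2.41 kb downstream), the ETS repressor Etv6 (46.3-fold and 47.2-fold, 413 bp upstream), the zinc finger gene Zfp608 (44.7-fold and 43.9-fold), Zfp458 and the neural factor Myt1 (47.6-fold and 42.9-fold, 288 bp upstream). Gfap, which encodes the intermediate filament of astrocytes, had 46.9-fold and 45.6-fold enrichment 687 bp upstream of its start, at chromosome 11, 102896698 to 102899076. Lmna, which encodes nuclear lamins, had 43.4-fold and 45.2-fold. The others were Tmem176b, Ccdc150, C1qtnf1, Gtf2a2, Tmc3, Rnf122, Rgs20, Nsmce1, Pih1d1, Xylt1, Lpo, Ndufa7 and Cdk5rap2.

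The strongest regions over 5 kb from every protein-coding start reached similar values. The region at chromosome 1, 82787315 to 82788110, had 53.9-fold and 60.4-fold enrichment and lay 10.5 kb upstream of the nearest listed start, that of the uncharacterised gene Gm19257. The region at chromosome 6, 108426372 to 108427378, had 51.8-fold and 51.7-fold and lay inside Itpr1, 29.3 kb from the nearest listed start, that of Gm27813. The one at chromosome 3, 154691884 to 154692959, had 50.8-fold and 57.1-fold and lay inside BC007180, 18.7 kb from its nearest listed start. A region of 50.4-fold and 49.4-fold at chromosome 10, 95142621 to 95144078, lay 181 kb downstream of the nearest listed start, that of Cradd. A region of 47.9-fold and 49.2-fold lay 6.28 kb upstream of Pou3f2, a POU-domain transcription factor of neural cells.

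Gene lists fixed in advance were compared with all other protein-coding genes for the share with a region within 5 kb of a start. Of 21883 protein-coding genes, 3958 (18.1%) had such a region. With the peaks of a single replicate, counted at either end of a gene, the number was 10906 for replicate 1 and 7618 for replicate 2. Odds ratios moved as well, from 9.11 to 35.3 for immediate early genes with replicate 1 alone. Known STAT3 targets had 27 of 35 genes with a region (77.1%, 95% Wilson interval 61.0 to 87.9%; Fisher's exact test, two-sided, adjusted p = 3.61e-13), among them Stat3, Socs3, Junb and Gfap with the strongest regions. Also bound were Fos, an AP-1 subunit, with 23.4-fold and 23.3-fold enrichment 161 bp downstream of its start, and Bcl3, a regulator of NF-kappaB, with 30.4-fold and 20-fold 1.53 kb upstream. Immediate early genes had 24 of 36 (66.7%, Fisher's exact test, adjusted p = 1.04e-09), where Junb, Gadd45g (38.3-fold and 37.1-fold), the AP-1 gene Fosl2 (32.1-fold and 30.6-fold) and the growth-arrest gene Btg2 (31.6-fold and 23.8-fold) were strongest. The Gadd45g region lay 2.64 kb downstream of a listed start, outside that transcript. The list of JAK-STAT and gp130 signalling genes had 14 of 44 (31.8%, Fisher's exact test, adjusted p = 0.0403), with Stat3, Socs3, Il6st and Cish strongest. That call ended in a permutation test against random lists matched on gene length (adjusted p = 0.128) and when either end of a gene was counted (Fisher's exact test, adjusted p = 0.0749). Of the known targets, 21 are in another list too, so these tests share genes.

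Transcription factors and progenitor markers of the oligodendrocyte lineage were bound more often than other genes, and myelin genes did not pass the test. Of 40 lineage transcription factors, 24 had a region (60%, 95% Wilson interval 44.6 to 73.7%; Fisher's exact test, adjusted p = 1.84e-08), with Tcf4 (30.6-fold and 26.3-fold), Sox5 (32-fold and 24.4-fold), Id2 (33.1-fold and 22.3-fold) and Zeb2 (27.3-fold and 22.3-fold) strongest. Olig2, a factor that specifies the lineage, had a region of 6.23-fold and 5.64-fold enrichment 93 bp upstream of its start and a stronger one, 36.7-fold and 27.6-fold, 8.01 kb downstream. Progenitor markers had 14 of 28 (50%, Fisher's exact test, adjusted p = 0.000259), led by Rnf122 (47.2-fold and 41.5-fold), Xylt1, Pcdh15 and Scrg1, and Pdgfra, the receptor for PDGF-AA, had 10.3-fold and 8.50-fold at 240 bp upstream. The progenitor call did not hold within 1 kb of a start (Fisher's exact test, adjusted p = 0.479), and against ribosomal protein genes neither the factors (adjusted p = 0.101) nor the progenitor markers (adjusted p = 0.534) passed. Myelin and mature oligodendrocyte genes had 11 of 36 (30.6%, Fisher's exact test, adjusted p = 0.0952), with Bcas1 (27.7-fold and 21.9-fold), Plekhb1, Trf and Cnp strongest. This list passed the threshold in 4 of 12 alternatives. They were an IDR of 0.01 or below (Fisher's exact test, adjusted p = 0.0204), the stronger 6462 regions (0.0119), the nearest start at any distance (0.00411) and a window of 25 kb (0.0214). Mbp, a main protein of myelin, had no region within 5 kb of a start and had regions of 14.7-fold and 11.5-fold at 33.1 kb and of 9.49-fold and 7.42-fold at 22.4 kb from the nearest listed start.

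Among lists of cellular processes, Notch, BMP and Wnt pathway genes had 22 of 40 (55%, Fisher's exact test, adjusted p = 4.74e-07), with Notch1 (29.5-fold and 27.2-fold), Id2, Bmpr1b and Hes5 strongest. Survival and apoptosis genes had 15 of 32 (46.9%, Fisher's exact test, adjusted p = 0.000333), with the tumour suppressor Trp53 (37.3-fold and 36.5-fold), Bbc3 (34.6-fold and 31.6-fold), the death receptor gene Fas and Mcl1 strongest. The Trp53 region lay 3.61 kb downstream of a listed start, outside that transcript. Cholesterol synthesis genes had 11 of 30 (36.7%, Fisher's exact test, adjusted p = 0.0254), led by Mvd, Srebf1, Abca1 and Insig2, and cell cycle genes had 13 of 38 (34.2%, adjusted p = 0.0274), led by Rb1 (38.5-fold and 35.9-fold), Cdkn2d, Ccnd1 and Ccnd2. Neither of the last lists passed a permutation test against random lists matched on gene length (adjusted p = 0.068 and 0.0646). Over all alternatives the cholesterol list kept its call in 8 of 12 and the cell cycle list in 6 of 12. The regions of Rb1 and Cdkn2d lay 1.69 and 3.10 kb downstream of a listed start, outside those transcripts. Interferon-stimulated genes had 12 of 40 (30%, Fisher's exact test, adjusted p = 0.0813; 0.0471 within 1 kb of a start), among them Irf2, Irf9, Irf1 and Stat2 with 22.5-fold or more in both replicates. Adjustment was by Benjamini-Hochberg over the 17 lists.

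Among markers of other cell types that a cortical culture could hold, those of astrocytes were bound more often than other genes. Astrocyte markers had 18 of 26 (69.2%, 95% Wilson interval 50.01 to 83.5%; Fisher's exact test, adjusted p = 4.96e-08), with Gfap, Atp1b2 (39.2-fold and 35.8-fold), Aldoc (30.6-fold and 24.7-fold) and Mlc1 (27.5-fold and 24.0-fold) strongest. The Atp1b2 region lay 2.21 kb downstream of a listed start, outside that transcript. Microglia markers had 3 of 26 (11.5%, Fisher's exact test, adjusted p = 0.646), which were P2ry12, Irf8 and Fcgr3, the last with a region of 2.43-fold and 2.18-fold from the weak group of 145. With the peaks of replicate 1 alone, counted at either end of a gene, microglia markers lay below other genes (5 of 26, Fisher's exact test, adjusted p = 0.00352). Neuron markers had 4 of 26 (15.4%, Fisher's exact test, adjusted p = 1), which were Map2, Tubb3, Gap43 and Gad1. Endothelial and fibroblast markers had 3 of 26 (11.5%, Fisher's exact test, adjusted p = 0.646), of which Cspg4 and Pdgfra are in the progenitor list too and Fn1 is the third. As references, ribosomal protein genes, which are active in dividing cells, had 30 of 75 (40%, 95% Wilson interval 29.7 to 51.3%; Fisher's exact test, adjusted p = 1.84e-05), with Rps28, Rpl22, Rps10 and Rpl13 strongest. The Rps28 region is the one named above for Ndufa7, inside that gene and 2475 bp upstream of Rps28. The Rpl13 region lay 4837 bp upstream of its start. Olfactory receptor genes had 4 of 1110 (0.36%, adjusted p = 6.67e-90, Fisher's exact test), which were Olfr1395, Olfr1414, Olfr90 and Olfr272. In a comparison chosen after the data were seen, known STAT3 targets (adjusted p = 0.00333), immediate early genes (adjusted p = 0.0383) and astrocyte markers (adjusted p = 0.0383) had a higher share than ribosomal protein genes by Fisher's exact test, and no other list did. By contrast, microglia markers, endothelial and fibroblast markers (adjusted p = 0.0308 for each) and olfactory receptors (adjusted p = 1.17e-33) had a lower one by Fisher's exact test. The higher share passed in 6 of 10 alternatives for the targets, 6 of 10 for immediate early genes and 3 of 10 for astrocyte markers. With the peaks of either replicate alone none of these lists passed. The direction for astrocyte markers turned with replicate 1 alone (odds ratio 0.846, Fisher's exact test, adjusted p = 0.752).

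**Figure D4:**
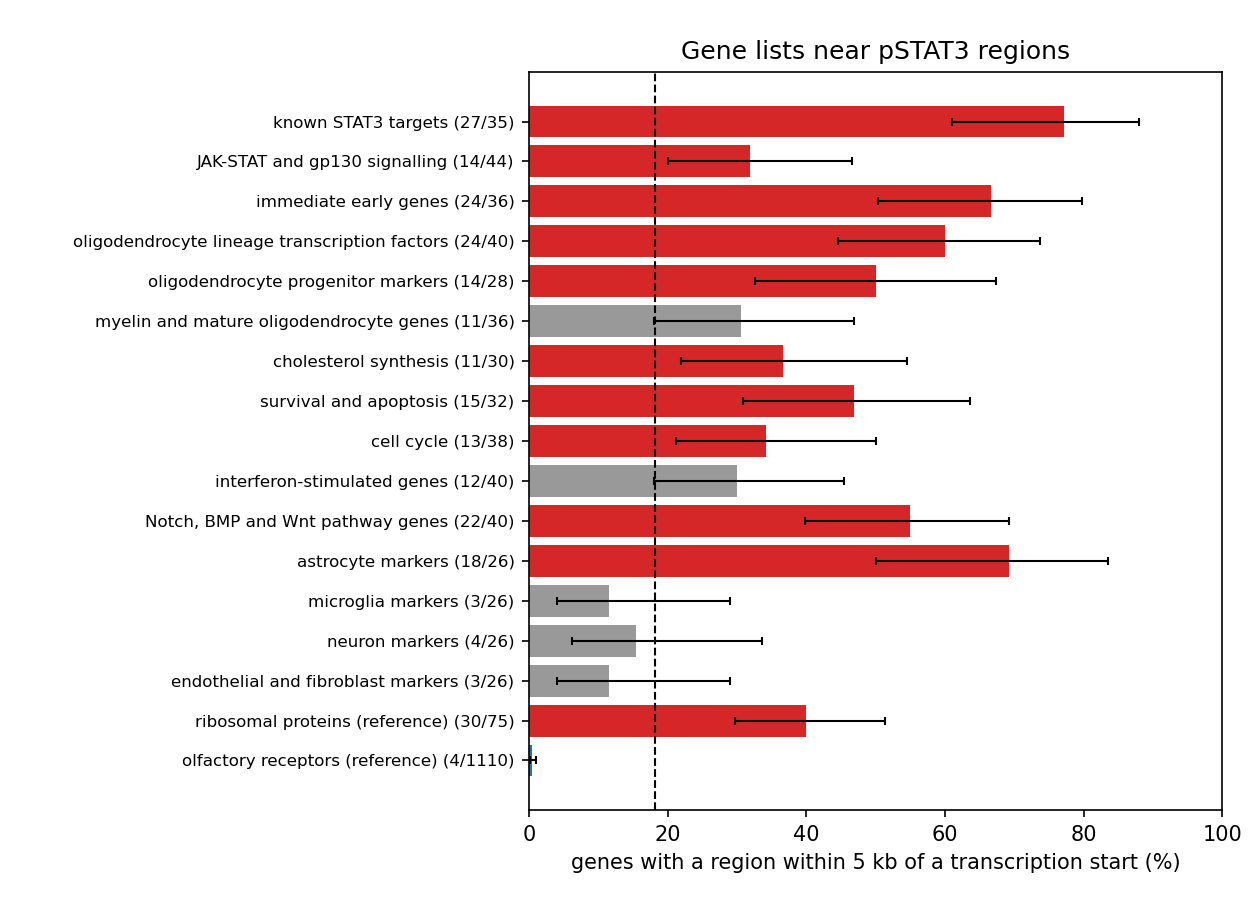
Percentage of each list's genes with a reproducible region within 5 kb of a transcription start (x axis), with 95% Wilson intervals as error bars and counts in the labels. Red bars lie above and the blue bar below other protein-coding genes with an adjusted p under 0.05, grey bars did not pass, and the dashed line marks all protein-coding genes, 18.1%. Known STAT3 targets reach 77.1% and olfactory receptors 0.36%.

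Regions were spread over all autosomes, at a mean of 5.28 ± 0.74 per Mb (SD over 19 autosomes), from 4.10 on chromosome 14 to 7.21 on chromosome 11. Per protein-coding gene the order was another, from 0.393 on chromosome 7 to 0.924 on chromosome 18, with 0.547 on chromosome 11 and an autosome mean of 0.647. Chromosome X had 193 regions (1.13 per Mb, 0.214 of the autosome mean) and chromosome Y had 3.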

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

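The test of strong peaks alone after thinning, the test of each list against ribosomal protein genes and the length-matched lists were chosen after results were seen, and the group of 145 weak regions was set apart at the widest gap after its values were seen. Peaks outside chromosomes 1 to 19, X and Y, which no comparison used, were counted in both lists. On the mitochondrial genome, replicate 2 had 14 peaks of 1.33-fold to 1.56-fold enrichment and replicate 1 had 0. On the scaffold JH584304.1, replicate 2 had 60 peaks of 1.50-fold to 3.24-fold enrichment and replicate 1 had 6. Other scaffolds held 52 peaks in replicate 1 and 38 in replicate 2, with values up to 27.1-fold and 20.5-fold.

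Replicate 1 had 1.58 times as many peaks as replicate 2. When the pileups of replicate 1 were thinned to 61.6% to match the background of replicate 2, 39899 ± 27 peaks (SD over 20 draws) still passed at the summit, 49.7% more than the 26649 of replicate 2, which argues against depth as the whole cause. Thinning does not model the caller's width limit; among peaks with a -log10 p of at least 15, 12866 were left against 9145 in replicate 2. At the reproducible regions, the ratio of pileup to background was lower in replicate 2 (median log2 difference -0.30), which is consistent with a weaker immunoprecipitation. No biological explanation was tested, since both libraries had the same treatment.

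Gene lists differed in the share of genes with a region near a start, and gene length is argued against for the known STAT3 targets, which exceeded length-matched random lists (two-sided permutation p = 0.0002, the smallest that 10000 lists can give). At the level seen in ribosomal protein genes, general accessibility of active promoters as the whole cause is argued against for the targets. This holds in the reproducible set within 5 kb of a start, where ribosomal protein genes reached 40%, with an interval below that of the targets. The intervals were apart in 6 of 10 alternatives too, and the other 4 leave it open: they overlapped for overlapping peaks and for either replicate alone, all counted at gene ends (70.7% against 85.7% without replicate 1, 86.7% against 97.1% without replicate 2) and within 25 kb. Ribosomal protein genes were the only reference for active promoters. Genes whose symbols begin with Eef (8 of 15, 53.3%) or Polr (13 of 28, 46.4%) had higher shares, and those with Mrpl (17 of 49, 34.7%) a lower one. These families were not compared with the targets, so accessibility above the ribosomal level stays open. For the JAK-STAT, cholesterol and cell cycle lists, 0 of 3 differed from ribosomal protein genes, so accessibility cannot be told apart from STAT3-specific binding there without a control immunoprecipitation. The lineage factor, progenitor, survival and Notch, BMP and Wnt lists did not differ from ribosomal protein genes either (Fisher's exact test, adjusted p = 0.101, 0.534, 0.604 and 0.299), so accessibility stays open for them too.

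A group of 145 regions with a mean -log10 p up to 6.22 was listed as reproducible, while 10009 pairs of overlapping peaks outside the set had a higher mean, 5910 of them below the next listed region at 11.5. This is consistent with selection by agreement of ranks at the weak end of the lists rather than by strength, although the gap that defined the group made this outcome probable. If the group were scattered at random, its share near starts was predicted to lie below that of the other regions. It did not: 34.5% (95% Wilson interval 27.2 to 42.5%) lay within 1 kb of a start, against 23.8% of the other regions (Fisher's exact test, two-sided, p = 0.0043). The group was compared only with the other regions, and no random placements of it were made. Fcgr3 is the microglia marker whose region, 2.43-fold and 2.18-fold, falls in the group of 145. No biological explanation was tested.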

How the results depend on the processing

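No paired analysis was possible because the inputs, which share replicate numbers with the ChIP libraries, were not analysed here and no result compares the groups. Alternatives chosen after seeing the data were the 25 kb window, either gene end, length-matched lists, ribosomal protein genes as the comparison, with all its settings, and removal of the 145 weak regions. The planned motif, GC and CpG alternatives and the 50 kb window were not run. Overlap of the replicates, the strength of shared peaks and the location against genes kept direction and call under every alternative run, with ratios over random placement from 1.83 to 5.59 for either end of a gene; starts were compared with 3' ends only. The number of regions was 23827 when replicate 1 peaks overlapping replicate 2 were taken, and Spearman's rho was 0.877 for overlap of at least 50% and 0.864 for -log10 p. Known STAT3 targets, immediate early genes, astrocyte markers and olfactory receptors kept their call in 12 of 12 alternatives, with odds ratios from 5.06 to 34.3 for the targets. Neuron markers passed in 0 of 12, at odds ratios on both sides of 1 (0.273 to 1.63).

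Other lists moved, as odds ratios; the cause was not tested. Against ribosomal protein genes they were 0.7 for JAK-STAT, 0.868 for cholesterol and 0.78 for cell cycle genes, all turned in direction, then 2.25 for lineage factors, 1.5 for progenitor markers, 1.32 for survival and 1.83 for Notch, BMP and Wnt genes, which lost the call, and 0.196 for microglia and for endothelial and fibroblast markers, which gained it. With length-matched lists the call was lost at 1.83 for JAK-STAT, 2.41 for cholesterol and 2.27 for cell cycle genes, and with either gene end at 1.95 for JAK-STAT and 1.70 for cell cycle genes. Within 1 kb it was lost at 1.48 for progenitor markers and 1.54 for cell cycle genes, and gained at 2.27 for interferon-stimulated genes. With the stronger 6462 regions it was lost at 2.29 for cholesterol and 1.71 for cell cycle genes, and gained at 3.05 for myelin and 2.66 for interferon-stimulated genes. With the nearest start at any distance it was lost at 2.00 for cholesterol, 1.90 for cell cycle and 1.56 for ribosomal protein genes, and gained at 2.92 for myelin genes. At an IDR of 0.01 it was gained at 2.53 for myelin and 2.18 for interferon-stimulated genes, and within 25 kb at 2.39 for myelin genes. Microglia markers were at 0.239 without replicate 2, where the call was gained, and at 0.445 without replicate 1; over all 12 alternatives they ranged from 0.196 to 0.76.

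The higher share than ribosomal protein genes was lost, as odds ratios, at 2.82 for STAT3 targets, 3.76 for immediate early genes and 1.28 for astrocyte markers with overlapping peaks, which like single replicates were counted at either gene end. Within 25 kb it was lost at 2.25 for targets and 2.36 for astrocyte markers, and within 1 kb at 1.81 for immediate early genes and 1.66 for astrocyte markers. Astrocyte markers also lost it at 3.08 with an IDR of 0.01 and at 2.54 with either gene end. With one replicate left out it was lost at 2.49 to 5.23 for targets and 3.32 to 5.38 for immediate early genes, and for astrocyte markers at 0.846, turned in direction, to 1.38. The cause was not tested.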

Other observations

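The family tests, the dense windows and the interferon cluster, with the genes named for them, were chosen after the data were seen. Other gene families went apart in the share of members with a region near a start. Grouped by the letters their symbols begin with, 15 of 152 families of at least 15 genes differed from other genes (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted), 6 upward and 9 downward. RNA-binding motif genes (Rbm) had 16 of 38 (Fisher's exact test, adjusted p = 0.0102), RNA polymerase subunits (Polr) 13 of 28 (adjusted p = 0.0102) and zinc finger genes (Zfp) 95 of 397 (adjusted p = 0.0328). Vomeronasal receptor genes (Vmn) had 0 of 355 (Fisher's exact test, adjusted p = 1.91e-29), cytochrome P450 genes (Cyp) 3 of 99 (adjusted p = 0.000716) and keratins (Krt) 1 of 53 (adjusted p = 0.0102).

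Some windows held many regions, counted by the nearest protein-coding gene among those listed. Among windows of equal size, the one with the most regions, 29, spanned 86500001 to 87000000 on chromosome 12, with Irf2bpl and Lrrc74a nearest to 4 regions each. The window around Socs3, 117500001 to 118000000 on chromosome 11, had 23 regions, with 8 of them nearest to Socs3. On chromosome 8 from 10500001, 4 of 20 regions were nearest to Irs2, an adaptor of insulin receptor signalling. On chromosome 4 from 97500001, 9 of 19 regions were nearest to Nfia, a gliogenic factor, and on chromosome 16 from 91000001, 4 of 17 were nearest to Olig1 and 3 to Olig2. Iqsec1, Pde4b and Tns3 each had 11 regions within 25 kb of a start, Fyn, Snd1 and Sox2 had 10, and Notch1, Gpr37l1 and Tcf4 had 9.

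The hypothesis that regions cluster was tested by the share with another region within 10 kb: it was 27.7% against a mean of 9.91% and a highest value of 11.4% for random placements (permutation p = 0.001, the smallest possible). The random placements ignore where genes lie, so part of the excess may come from gene density. The hypothesis that known STAT3 targets have stronger regions was tested on the strongest region of each gene: the median was 20.0-fold for 27 targets against 7.94-fold for 3931 other genes with a region (permutation p = 1e-05, the smallest possible). A gene with more regions or listed starts has more values to take the strongest from, and genes were not matched on these numbers.

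Whether the regions at astrocyte genes such as Gfap, Aldoc and Mlc1 come from progenitors or from astrocytes in the culture was not tested.

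Of genes ranked by the number of regions within 25 kb of a start, Ifnz in the type I interferon cluster of chromosome 4 had the most, 15, from 88757459 to 88806427. They were spaced by a median of 2.96 kb and had a lower fold enrichment of 4.35 to 9.22, with medians of 9.29 in replicate 1 and 5.37 in replicate 2. The count is not particular to Ifnz, since the 25 kb windows of neighbouring genes overlap. How reads that align at several places were handled is not given. Whether the evenly spaced, weak regions are separate binding sites was therefore not tested. Gm13272 and Gm13276 of the same cluster had 14 regions each.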
